A study of Mus musculus with 12 samples.

How the data were processed

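Messenger RNA was measured in 12 mouse heart libraries, 3 from each of 4 groups: control and mutant hearts at postnatal day 10 (P10), and control and mutant hearts at 7 months. Per the labels' protocols, hearts were frozen, RNA was extracted with TRIZOL, and libraries were made with a stranded kit from poly-A RNA. All animals carried the floxed Jarid2 allele on both chromosomes. Mutants carried in addition an allele written with the letter C at the aMHC transgene, read here as Cre recombinase under the alpha myosin heavy chain promoter, which is active in heart muscle cells. Presence of this allele and the label mutant therefore coincide in every library.

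The deposited files are gene tables of RSEM, a program that assigns reads to transcripts. Bowtie 1.1.2, RSEM 1.3.0 and the mouse build GRCm38.p6 are named in the submitters' processing notes. Per the file headers, each table gives an estimated count, TPM (transcripts per 1000000 transcripts) and an effective length for each gene. There were 24 tables, 2 sequencing lanes for each library, with 25098 gene rows each. Rows are named by RefSeq class and symbol, NM for coding and NR for non-coding transcripts, so that 585 symbols have both an NM and an NR row. The deposited estimated counts need not be whole, because RSEM divides reads that match several transcripts. The deposited TPM values were not used in a test. Filters, the strand setting of the counting and the annotation release are not given in the sources used here. Reads of near-identical copies, of overlapping genes and of antisense partners may have been divided in ways that the tables do not show.

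The estimated counts of both lanes were summed and then rounded to whole numbers. Lanes of the same library differed by a chi-square per degree of freedom of 1.16 to 2.17, and deep replicates of the same group by 16.4 to 134, so no pair of deep libraries was taken for a duplicate. P10 control 2 differed from P10 controls 1 and 3 by 2.28 and 1.91, and at its depth this measure cannot tell a replicate from a lane. Totals were 37624037 to 52926715 estimated counts in 11 libraries and 241419 in P10 control 2. In P10 control 2 a single read is worth 4.14 CPM (counts per 1000000 counts of the library), and 3 counts, taken as the floor of detection, are worth 12.4 CPM. In the other libraries 3 counts are worth under 0.08 CPM. These values are before scaling. Counts include PCR copies, so intervals and floors cover counting error alone. CPM values of genes are scaled by the TMM factors of the test below, and on that scale a read of P10 control 2 is worth 3.33 CPM. Group means of CPM weight the 3 libraries equally, while fitted fold changes follow the counts, so P10 control 2 moves a mean of a low gene far more than its fold change.

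Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust dispersions, TMM normalization) in R 4.3.3, with limma 3.58.1. All 12 libraries entered a common fit with 1 mean per group and 8 residual degrees of freedom. The filter of edgeR by group (minimum count 10) kept 15478 rows and left out 9620. P-values are two-sided and adjusted by Benjamini and Hochberg over all rows tested, with 0.05 as the threshold. A gene is called, and is said to rise, fall or change, only past that threshold. Adjusted p-values below are from this test unless another tool is named. Of the tested rows, 15437 matched a RefSeq gene of GRCm38.p6, 284 of them by an older symbol, and coordinates are from that table. The comparisons were mutant against control at P10, the same at 7 months, the difference between these effects (the interaction), and 7 months against P10 in controls. The labels do not say that the replicates are separate animals beyond their numbers, so p-values measure the spread between these samples.

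Before the data were examined, 47 gene lists were written from textbook knowledge, and the designs, the alternatives and the rule for named genes were fixed. Of the lists, 45 had at least 3 tested members. They were tested with camera (preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance one way, and does not compare the list with other genes. Genes were named per comparison by this rule: past the threshold, not a predicted or clone name, at least 1 CPM in a group compared, and all replicates of a group above all of the other. From these came the 10 largest changes each way. For the interaction it was 5 each way, without the last condition. Jarid2, Nppa, Nppb, Myh6 and Myh7 were named whatever their p. Of the genes this rule picks, 2 are not reported here and were not replaced. From each list described, up to 4 members were to be named, called ones first. Which lists to describe, and the limit of 2 members, were chosen after the list results were seen, and a few other genes named as such were chosen after their values were seen. Where a group had no count, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts, a ratio is given with its exact 95% counting interval.

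The fit was tested on simulated counts of the 15478 rows. For each comparison 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, picked among rows with a mean of at least 1 CPM. Dispersions came from the fit of the real counts by group, and means from the real counts of each stage. Rows were drawn independently. The shares below therefore do not cover lower rows or differences that many genes of a library have in common. At P10, 34.3% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 11 of 144 calls were of unchanged genes. At 7 months the shares were 41.8%, 74.6% and 98.5%, with 12 of 155 calls of unchanged genes. For the interaction they were 8.96%, 52.2% and 90.9%, with 2 of 103. For age they were 41.8%, 70.1% and 97.0%, with 11 of 150.

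The alternatives were DESeq2's size factors in edgeR, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with sample weights, a fit of the compared libraries alone, the replicate number as a block, each lane alone, effective lengths as an offset, mitochondrial and globin genes left out, and each library left out. After the data were seen, 2 were added: NM and NR rows of a symbol summed, and the male share of each library as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.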

Results

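The study compared hearts of mice in which the floxed Jarid2 gene was deleted in heart muscle with hearts of control littermates, at postnatal day 10 (P10) and at 7 months. Jarid2 encodes a partner of Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates lysine 27 of histone H3. Dilated cardiomyopathy, the condition the study names, is an enlargement of the heart chambers with weak contraction. Each of the 4 groups held 3 libraries of poly-A RNA from mice of mixed 129/Svj and C57BL/6 background. In the order of the replicate numbers, total estimated counts were 37624037, 241419 and 42111177 in P10 controls and 37710274, 52926715 and 48254783 in P10 mutants. At 7 months they were 43047936, 45740229 and 41924169 in controls and 44269448, 51114000 and 49013552 in mutants. P10 control 2 was thus 183 times shallower than the median of the others.

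Stage was the largest source of spread. The first principal component, with 53.6% of the variance, separated the P10 from the 7-month libraries, and the second, with 26.5%, set P10 control 2 apart. With that library left out, the second component (14.7%) held the 3 mutants of 7 months between 7.34 and 25.1 and the 3 controls of that age between -17.3 and -9.21. Mitochondrial transcripts took 30.1% ± 2.74 (SD, n = 3) of the counts in P10 controls and 36.3% ± 0.23 in P10 mutants. Globin transcripts took 1.00% ± 0.135 and 0.580% ± 0.108. Both differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. At 7 months the mitochondrial share was 40.9% ± 5.5 in controls and 37.0% ± 3.60 in mutants (exact permutation p = 0.4, n = 3 each), and globin gave an exact permutation p of 0.9.

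Jarid2 itself (NM row, chromosome 13, 44730774 to 44921643, GRCm38.p6) was measured in every library first, because it bears on the genotype labels. P10 controls held 32.4, 33.3 and 36.9 CPM and P10 mutants 36.1, 41.7 and 33.4, a log2 fold change of 0.10 (SE 0.11) with an adjusted p of 0.72. At 7 months Jarid2 fell by 0.55 on the log2 scale (SE 0.11, adjusted p = 0.00369), from 17.3 ± 0.598 CPM in controls to 11.8 ± 1.23 in mutants (SD, n = 3), with all mutants below all controls. The interaction was -0.65 (adjusted p = 0.024). It lost its call without P10 control 1, P10 mutant 2, 7-month control 2 or 7-month mutant 3, with adjusted p up to 0.0996. The call also ended with the replicate number as a block. The row counts all exons of the gene in all cells of the heart, and the floxed exons are not given in the sources used here, so the count can stay high after a deletion in muscle cells. At P10 it does not tell the libraries labelled mutant from those labelled control, and directions at P10 rest on the labels.

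**Figure D1:**
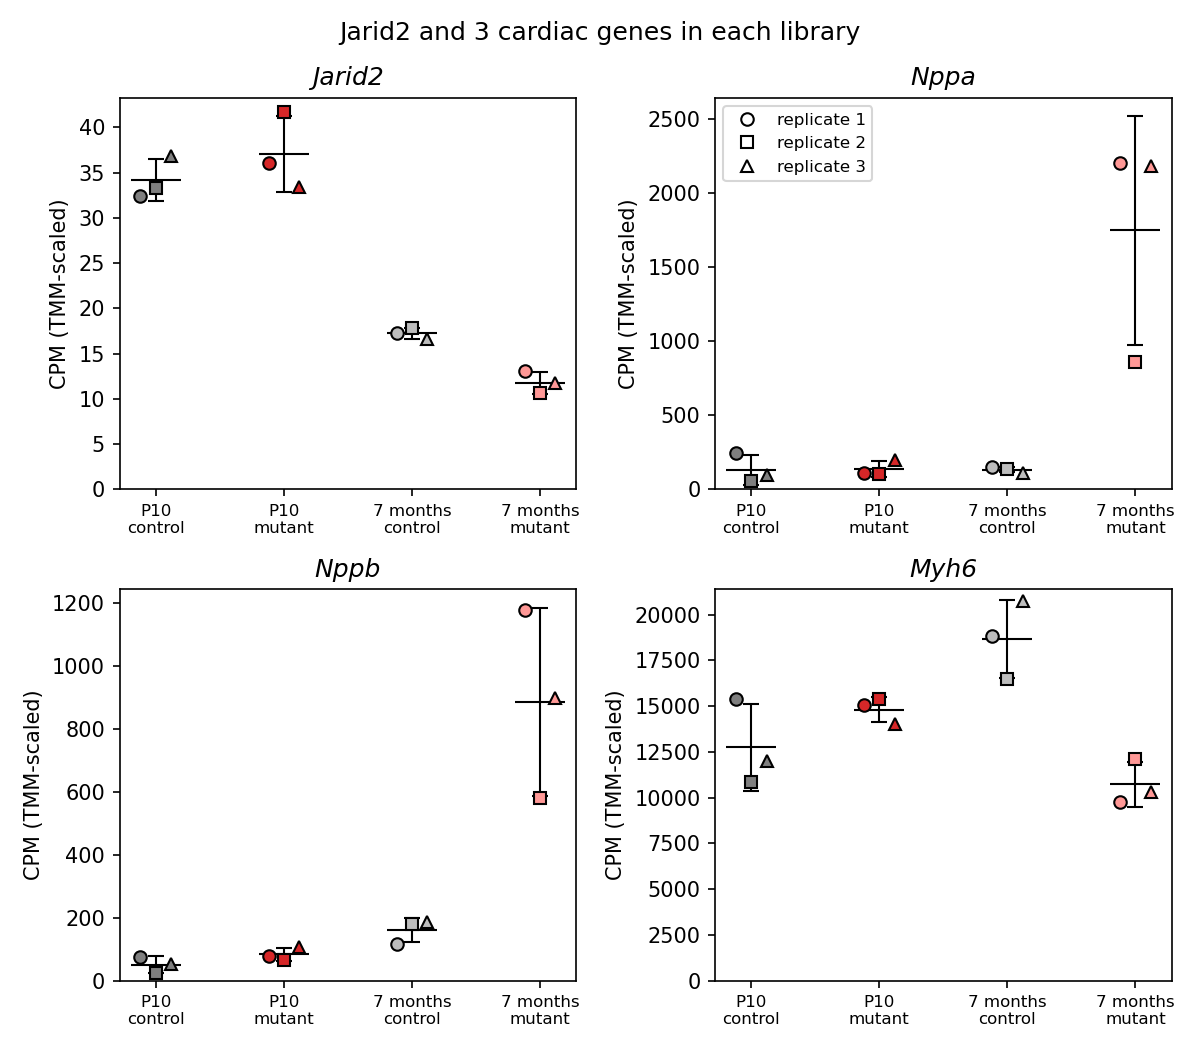
Each panel shows the CPM of 1 gene (Jarid2, Nppa, Nppb, Myh6) on a linear axis from 0, with a point per library, a horizontal line at the group mean and bars of 1 SD (n = 3). The marker shape gives the replicate number, which was not taken to pair samples. Jarid2 separated the genotypes at 7 months (17.3 against 11.8 CPM) and not at P10 (34.2 against 37.1), while Nppa and Nppb were high in the 7-month mutants.

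At P10 few genes passed the threshold between the hearts labelled mutant and controls. The homeobox genes Irx2 and Irx1, transcription factors that pattern the embryo and neighbours on chromosome 13, rose. Irx2 (72624430 to 72634196) went from 2.29 ± 0.974 to 7.20 ± 1.19 CPM (log2 fold change 2.00, SE 0.23, adjusted p = 0.00463). Irx1 (71958232 to 71963723) went from 0.689 ± 0.649 to 3.42 ± 0.328 CPM (1.74, SE 0.26, adjusted p = 0.0391). In P10 control 2 the Irx2 value is 1 read (3.33 CPM) and Irx1 had none. P10 controls 1 and 3 held 1.40 and 2.15 CPM of Irx2 and 0.776 and 1.29 CPM of Irx1. Lrig1, a membrane protein that restrains growth factor receptors, rose by 0.83 (adjusted p = 0.0443), the guidance molecule Ntn1 by 0.83 (0.0443) and Bves, a membrane protein of heart muscle, by 0.63 (0.0403). The death-associated kinase Dapk1 fell by 0.65 (0.0403).

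In all, 9 of 15478 rows were called at P10, 8 higher and 1 lower, and 1897 had an unadjusted p under 0.05. The remaining calls were the non-coding transcript 9330158H04Rik (log2 fold change 1.20, adjusted p = 0.0391, a clone name outside the naming rule) and the coding rows of Ano4, of the anoctamin family of channels and lipid scramblases, and of Fam120b. Ano4 had no count on its coding row in P10 controls and 296 counts in P10 mutants, at least 62.7-fold higher (32.7 and 30.2 without control 1 or 3), and Fam120b rose by 1.67 (adjusted p = 0.0391). With coding and non-coding rows summed, an alternative chosen after the data were seen, Ano4 came to 0.34 (adjusted p = 0.51) and Fam120b to -0.10 (0.661), and neither was called. That setting called 8 genes, the other 7 and the stress gene Ankrd1 (1.27, adjusted p = 0.0398), which stood at 1.27 with 0.0536 in the unsummed fit. The P10 count depended on the tool and on every library: DESeq2 called 33, voom 38 and a fit of the P10 libraries alone 51, while leaving out control 1 left 1 call, control 3 left 3 and any other P10 library 2. Of the 8 called genes under the naming rule, Ano4 kept its call in all 6 of these fits, Irx2 lost it without control 1 alone (adjusted p = 0.176), and Irx1, Fam120b, Lrig1, Ntn1, Bves and Dapk1 lost it without any 1 of the 6 (adjusted p up to 0.77).

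The hallmark cardiac genes were not called at P10. Nppa and Nppb encode the natriuretic peptides, and Myh6 and Myh7 the adult and fetal heavy chains of mouse ventricular myosin. Their log2 fold changes were -0.13 (SE 0.52, adjusted p = 0.945), 0.48 (SE 0.33, 0.572), 0.22 (SE 0.15, 0.556) and -1.06 (SE 1.05, 0.692). In the order of the replicate numbers, Myh7 held 682, 286 and 318 CPM in P10 controls and 150, 32.8 and 459 in P10 mutants. The atrial gene Myl7, looked at after its values were seen, held 231.5, 23.3 and 157 CPM in controls and 106, 34.0 and 214 in mutants. How much atrial tissue each P10 library held is not known.

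Among gene lists, camera called 13 of 45 at P10, 9 higher and 4 lower, although only Irx1 and Irx2 among their members were called one by one. Camera with an estimated correlation called 0, with 4 lists at an unadjusted p under 0.05, and fry called 1. Mitochondrially encoded proteins were higher (median 0.50, 13 tested, none called, 7 higher when adjusted over the list alone), for example mt-Atp6 at 0.67 and mt-Nd4 at 0.49 (adjusted p = 0.47 with an estimated correlation). This went with the larger mitochondrial share of the P10 mutants given above. The enzymes of the tricarboxylic acid cycle had a median of 0.25 over 18 tested, with Suclg2 at 0.58 and Mdh1 at 0.40. None was called and 1 was higher adjusted over the list alone (adjusted p = 0.697 with an estimated correlation). Dilated cardiomyopathy disease genes had a median of 0.14 over 24 tested, none called and 5 higher adjusted over the list alone, with Ankrd1 at 1.27 and cardiac actin Actc1 at 0.47. Their camera result did not hold with an estimated correlation (adjusted p = 0.065 with an estimated correlation), while fry gave 0.012.

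Developmental regulators that PRC2 binds in many tissues had a median of 0.55 at P10, with 2 of 17 called, Irx1 and Irx2, and 4 higher adjusted over the list alone (adjusted p = 0.286 with an estimated correlation). The median was 0.28 without P10 control 1. Cardiac transcription factors had a median of 0.14 and a mean of 0.55 over 21 tested, with none called and 2 higher adjusted over the list alone (adjusted p = 0.286 with an estimated correlation). The mean rests in part on Hand1, with no count in P10 controls and at least 13.6-fold higher in mutants (7.07 and 6.53 without control 1 or 3, adjusted p = 0.108), and Esrrg stood at 1.14. The median did not change with Hand1 at its bound, and was 0.08 without P10 control 1. Calcium handling had a median of 0.24 over 19 tested, with the exchanger Slc8a1 at 0.62 and the kinase Camk2d at 0.52. None was called and 2 were higher adjusted over the list alone (adjusted p = 0.286 with an estimated correlation). The median was 0.14 without P10 control 3. Endothelial markers were lower (median -0.13 over 14 tested, Egfl7 -0.49 and Vwf -0.56). None was called and 4 were lower adjusted over the list alone (adjusted p = 0.697 with an estimated correlation). The median was -0.08 without P10 control 1. Cell cycle genes were lower (median -0.20 over 31, Mcm5 -0.31, Birc5 -0.49), with none called under either adjustment, the list alone included (adjusted p = 0.73 with an estimated correlation). Their list call ended without P10 control 1 (median -0.06, adjusted p = 0.192) or P10 mutant 1 (median -0.06, 0.504), and the median was -0.32 without P10 control 3 and -0.40 without P10 mutant 3. The other list calls at P10 were cardiac stress genes (median 0.21), adult sarcomere (0.16), ketone and branched-chain amino acid breakdown (0.23), Hox genes (-0.42) and the Notch pathway (-0.27), with adjusted p of 0.711, 0.565, 0.697, 0.697 and 0.697 with an estimated correlation. No member of these lists was called, and 1 stress gene and 1 sarcomere gene were higher adjusted over the list alone.

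At 7 months mutant hearts differed broadly from controls. The natriuretic peptide genes and most listed matrix, stress and heat shock genes rose, and most listed genes of fatty acid oxidation, the tricarboxylic acid cycle and ketone use fell. No list result at 7 months held with an estimated correlation. Nppa rose from 133 ± 17.8 to 1745 ± 769 CPM (log2 fold change 3.72, SE 0.55, adjusted p = 0.0028), and Nppb from 161 ± 39.2 to 886 ± 300 CPM (2.46, SE 0.33, adjusted p = 0.00113). Myh6 fell by 0.80 (SE 0.15, adjusted p = 0.00299). Myh7 stood at 1.83 with an SE of 1.05 and was not called (adjusted p = 0.261), since its 3 controls ranged from 195 to 1051 CPM and its 3 mutants from 718 to 3270.

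In total 2949 rows were called at 7 months, 1522 higher and 1427 lower, with 5252 at an unadjusted p under 0.05. DESeq2 called 1891, voom 6194 and the 7-month libraries alone 1826. The count was 1909 without control 2, 1719 without control 3, 1729 without mutant 1 and 1638 without mutant 3, and it stayed within 1.5 times without control 1 or mutant 2. Among the largest rises under the naming rule, beside Nppa, were the inducible heat shock genes Hspa1a (5.17, adjusted p = 0.0183) and Hspa1b (4.97, 0.0218), which are near-identical copies that share reads. Hspa1a held 298 CPM in mutant 1 and 12.9 and 32.9 in the others, against 1.47 to 5.21 in controls. Without mutant 1 the 2 genes stood at 2.86 and 2.67, and Hspa1b at 5.58 without control 3. Both calls were lost without any single 7-month control (adjusted p up to 0.0715 and 0.0833). Others were Serpinb1c (4.55), the cartilage matrix protein Cilp (3.92), Sprr1a (3.76), the lipoprotein receptor Lrp8 (3.74), Mgam (3.65) and the homeobox gene Prrx2 (3.65), each with an adjusted p of 0.00251 or less. Prrx2 stood at 4.36 without control 2 and at 2.90 without mutant 1.

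Among the largest falls were the acyl-CoA synthetase Acsm5 (-3.16), the glycolytic regulator Pfkfb1 (-2.93, from 23.1 ± 2.02 to 3.03 ± 1.53 CPM), Tmem150c (-2.86), the antisense transcript Uckl1os (-2.57), Epop, a PRC2-associated protein (-2.54), the channel subunit Cngb3 (-2.35) and Amph (-2.21), each with an adjusted p of 0.00184 or less. The strand setting of the counts is not given in the sources used here, so Uckl1os cannot be separated from Uckl1. Non-coding rows of Abhd10 (-2.52) and Gzmm (-2.20) were also among the 10 largest falls, but with both rows summed they came to -0.20 (adjusted p = 0.24) and -0.08 (0.804). The Abhd10 call was lost too without control 2, mutant 1 or mutant 3 (adjusted p up to 0.0951).

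Camera called 19 of 45 lists at 7 months, 13 higher and 6 lower, and with an estimated correlation 0, with 5 at an unadjusted p under 0.05, while fry called 19. Each list is therefore given by the count of its members and their median. Of 32 extracellular matrix genes, 29 rose and none fell (median 1.58), among them Cilp (3.92) and the latent TGF-beta binding protein Ltbp2 (3.63, adjusted p = 0.00545, and 2.91 without mutant 1). Adjusted over the list alone, 31 were higher (adjusted p = 0.3 with an estimated correlation). Fibroblast markers rose in 6 of 11 (median 0.49), including the collagens Col1a1 (1.41) and Col3a1 (1.39, from 187 ± 73.9 to 492 ± 65.4 CPM), and 7 were higher adjusted over the list alone (adjusted p = 0.3 with an estimated correlation). Macrophage markers rose in 10 of 15 (median 0.50), including the complement gene C1qb (0.96) and lysozyme Lyz2 (0.94), with 12 adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Inflammation and acute phase genes rose in 6 of 15 (median 0.53, Serpina3n 1.34, Lcn2 1.24), with 7 adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Endothelial markers had a median of -0.20 with 2 of 14 lower, the receptors Kdr (-0.98) and Flt1 (-0.71), and 5 lower adjusted over the list alone. That list was not called (adjusted p = 0.0876, and 0.741 with an estimated correlation). It was called without control 1 (0.000646) or mutant 3 (0.0153), and its median was -0.13 without mutant 2.

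Most listed genes of fatty acid oxidation, ketone use and the tricarboxylic acid cycle fell in 7-month mutants, as did 15 of 35 nuclear genes of oxidative phosphorylation. None of these list results held with an estimated correlation. Glycolysis genes went both ways, with 3 that rose and 6 that fell of 23 and 4 and 7 adjusted over the list alone (median -0.02, not called, adjusted p = 0.546, and 0.919 with an estimated correlation). Fatty acid oxidation genes fell in 19 of 25 and rose in none (median -0.64), among them Etfdh, which passes electrons to the respiratory chain (-0.97, adjusted p = 0.00266), and Ech1 (-0.92). Adjusted over the list alone 21 were lower (adjusted p = 0.308 with an estimated correlation). Genes of ketone and branched-chain amino acid breakdown fell in 12 of 14 (median -0.70), led by Bdh1, which interconverts ketone bodies (-1.91, from 108 ± 13.8 to 28.8 ± 3.19 CPM), and Ppm1k, the phosphatase that activates branched-chain ketoacid oxidation (-1.29). The same 12 of 14 were counted adjusted over the list alone (adjusted p = 0.3 with an estimated correlation). Tricarboxylic acid cycle genes fell in 15 of 18 (median -0.51, Sucla2 -0.81, Idh2 -0.76), and in 18 adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 15 of 35 (median -0.29, Ndufs1 -0.74, Uqcrc2 -0.62), and in 16 adjusted over the list alone (adjusted p = 0.498 with an estimated correlation). Of 13 mitochondrially encoded proteins 1 fell, under either adjustment and over the list alone as well (median -0.33, adjusted p = 0.802 with an estimated correlation), mt-Nd6 at -0.60, and mt-Co1 stood at -0.40. The mt-Nd6 call was lost without control 2, control 3, mutant 1 or mutant 3 (adjusted p up to 0.108) and in a fit of the 7-month libraries alone (0.0763). The list call ended without control 2 (median -0.18, adjusted p = 0.211) or mutant 1 (median -0.21, 0.183), and the median was -0.55 without control 1. Mutant 1 stood apart in these libraries. The fatty acid oxidation list averaged -0.88 in mutant 1, -0.36 in mutant 2 and -0.59 in mutant 3 against the control mean, and the atrial marker list 2.34, 0.45 and 0.73. Of the atrial genes, looked at after their values were seen, Myl7 held 216 CPM in mutant 1 and 9.31 and 14.1 in the others.

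Called members of the stress, p53, cell cycle and immediate early lists were mostly higher at 7 months, and no list held with an estimated correlation. Cardiac stress genes rose in 11 of 16 (median 1.79), among them Nppa and the circulating factor Gdf15 (3.17, adjusted p = 0.00372, and 2.28 without mutant 1), with 13 adjusted over the list alone (adjusted p = 0.3 with an estimated correlation). Gdf15 held 12.5 CPM in mutant 1 and 1.98 and 4.96 in the others. Heat shock proteins rose in 7 of 11 and fell in 1 (median 1.42, led by Hspa1a and Hspa1b), with 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.353 with an estimated correlation). The median was 0.90 without mutant 1. Unfolded protein response genes rose in 9 of 13 (median 0.38, Sdf2l1 1.40, Creld2 0.89), with 10 adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Integrated stress response genes rose in 5 of 15 and fell in 1 (median 0.48, Gdf15 3.17, Mthfd2 0.92), with the same 5 and 1 counted adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). The median was 0.28 without mutant 3. Targets of p53 rose in 5 of 14 (median 0.26), among them the cell cycle inhibitor Cdkn1a (1.48, adjusted p = 0.000511) and Phlda3 (1.39), with 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Cell cycle genes rose in 12 of 31 (median 0.59), with 15 adjusted over the list alone (adjusted p = 0.498 with an estimated correlation). Of these, Aurkb (1.32) lost its call without control 3, mutant 1 or mutant 3, and Ccnb1 (1.18) without mutant 1 or mutant 3. Lcn2 lost it without control 3 or mutant 3. Immediate early genes rose in 3 of 17, also adjusted over the list alone (median 0.44, Egr2 2.20, Nr4a3 2.01, adjusted p = 0.803 with an estimated correlation). That list call ended without control 1 (adjusted p = 0.186) or mutant 1 (median 0.01, 0.512) and with the replicate number as a block (0.0799). Egr2 was not called without control 1, control 3 or mutant 1 (1.49 without the last), and stood at 2.86 without control 2. Nr4a3 was not called without control 1, control 2 or mutant 1 (1.26 without the last), and stood at 2.70 without control 3. Both calls ended with the block (adjusted p = 0.154 and 0.089) and in a fit of the 7-month libraries alone (0.0688 and 0.114), that of Egr2 with no filter (0.0525) and that of Nr4a3 with voom (0.128).

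Genes of contraction and excitation went both ways at 7 months. Calcium handling genes fell in 8 of 19 and rose in 1, with 10 and 1 adjusted over the list alone. The release channel Ryr2 stood at -0.76 and Sypl2 at 1.15. The median was -0.30 and camera's direction was down, while the mean was 0.09 (adjusted p = 0.333 with an estimated correlation). The list call ended without control 2 (adjusted p = 0.0521) or mutant 3 (0.0778), and the Sypl2 call without control 2. Of 25 ion channel and conduction genes 4 rose and 7 fell, under either adjustment and over the list alone as well, and the list was not called (adjusted p = 0.557, and 0.803 with an estimated correlation). Within it Kcne1, the small subunit of the slow delayed rectifier potassium channel, rose from 7.79 ± 0.763 to 60.3 ± 9.75 CPM (log2 fold change 2.95, SE 0.13, adjusted p = 6.28e-08), and Kcnd2, a pore subunit of the transient outward current, fell by 1.91 (0.00885), and by 2.66 without mutant 2. Adult sarcomere genes rose in 1 and fell in 3 of 20, also adjusted over the list alone (median -0.18, Myh6 -0.80, Tnni3 -0.56). That list was just short of its threshold (adjusted p = 0.0518, and 0.498 with an estimated correlation) and passed it without control 2 (0.00917) or control 3 (0.0472), and the Tnni3 call was lost without mutant 1. Fetal and skeletal sarcomere isoforms rose in 2 of 12, also adjusted over the list alone (median 1.11, adjusted p = 0.498 with an estimated correlation), namely Tnni1 (2.94, from 0.260 to 1.99 CPM) and skeletal actin Acta1 (2.49). The atrial genes Myl7 and Myl4 are members too and were not called. Myl4 held 279 CPM in mutant 1 and 23.3 and 25.8 in the others. The mean log2 CPM of the list was 4.55, 3.08 and 3.46 in mutants 1, 2 and 3, and that of the atrial markers 4.88, 2.99 and 3.27. The Acta1 call was lost without control 2, control 3, mutant 1 or mutant 3, and the list call without control 2 (adjusted p = 0.103) or mutant 1 (0.157).

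Developmental regulators under PRC2 rose in 4 of 17 at 7 months, also adjusted over the list alone (median 0.39), with the homeobox gene Dlx5 at 3.27 (2.66 without control 1 and 5.32 without control 3) and Tbx15 at 2.50 (3.27 without control 1). Both had under 1 CPM in either group. The list was not called (adjusted p = 0.0774, and 0.498 with an estimated correlation), but was without control 3 (0.0247) or mutant 2 (median 0.61, adjusted p = 0.0179), and its median was 0.24 without mutant 1. Cardiac transcription factors fell in 4 of 21, with 1 higher and 7 lower adjusted over the list alone (median -0.23, Esrrb -0.64, Mef2a -0.45), and were not called (adjusted p = 0.128, and 0.498 with an estimated correlation). Their median was -0.08 without control 2. The Mef2a call was lost without control 2, control 3, mutant 1 or mutant 3. Of 10 PRC2 components none was called at either stage, under either adjustment and over the list alone as well (camera adjusted p = 0.584 at P10 and 0.809 at 7 months). Genes tied to Jarid2 in earlier heart work rose in 2 of 4, also adjusted over the list alone: Nppa and the growth factor Nrg1 (3.06, adjusted p = 0.00124). That list was called (median 1.56, adjusted p = 0.481 with an estimated correlation), and the call ended without control 1 (adjusted p = 0.108) or mutant 1 (0.133).

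**Figure D2:**
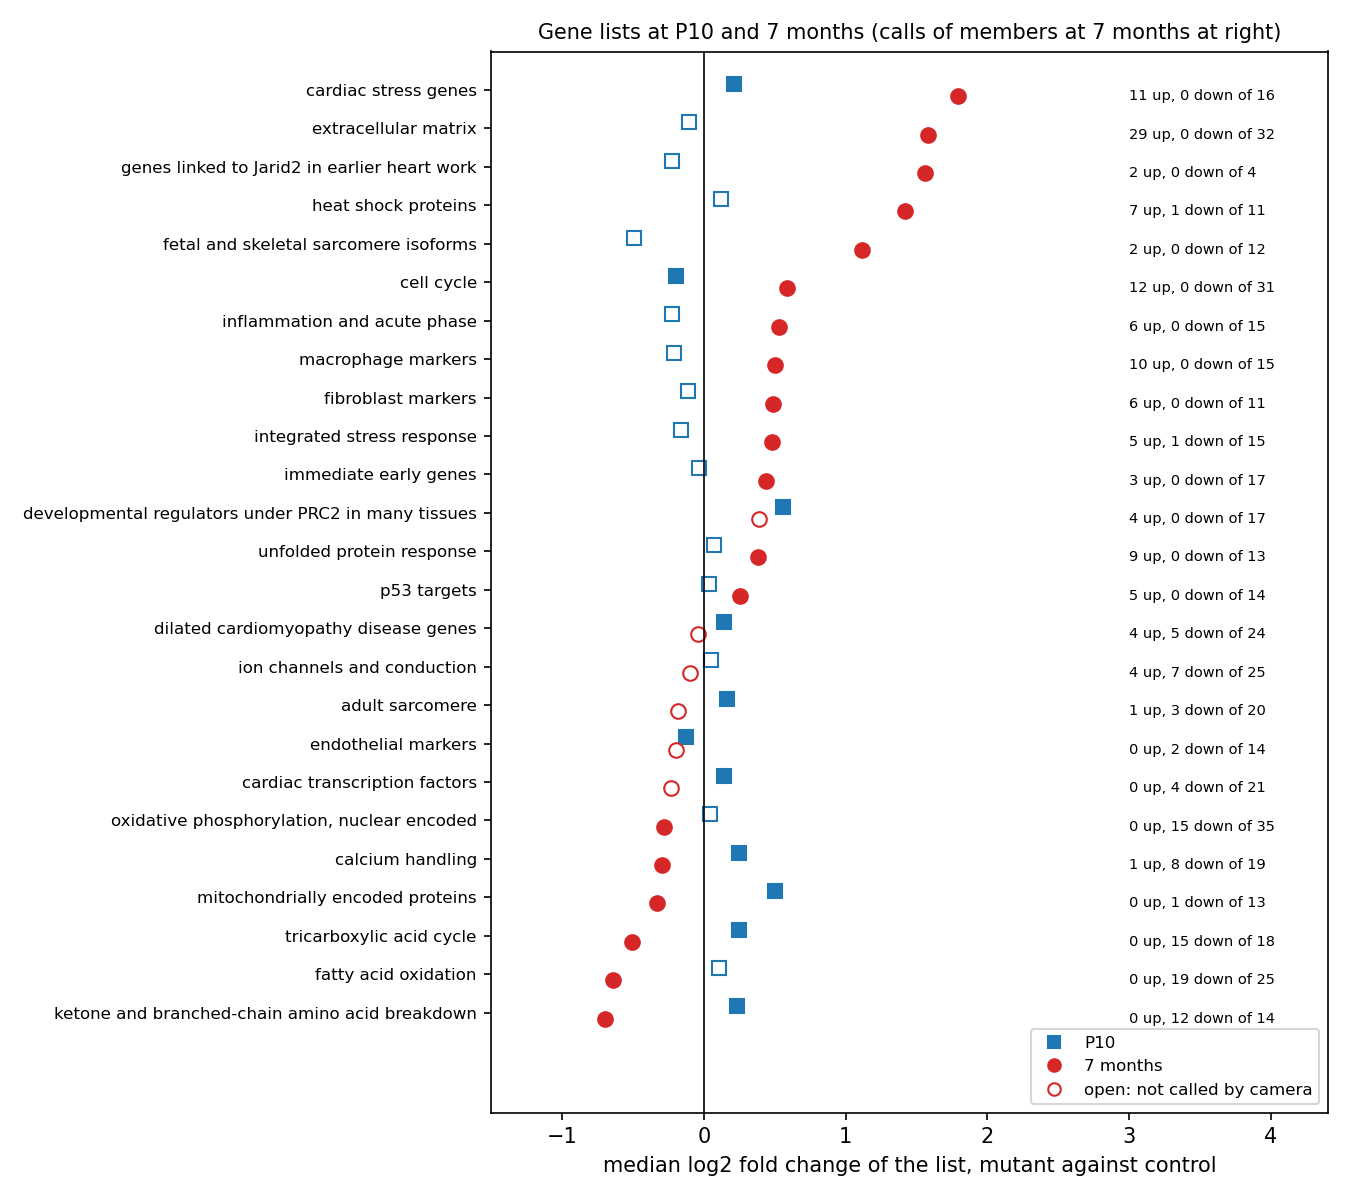
Median log2 fold change of mutant against control (x axis) for each gene list (y axis), at P10 (blue squares) and 7 months (red circles), with filled symbols for lists called by camera and the calls of members at 7 months at the right. Extracellular matrix (1.58) and cardiac stress genes (1.79) lie far right at 7 months and the lists of fat and ketone use, tricarboxylic acid cycle and nuclear oxidative phosphorylation (-0.29 to -0.70) left of 0, while P10 medians stay between -0.49 and 0.55; no genotype list result held with an estimated correlation.

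The genotype effect itself differed between the stages. The interaction called 1454 rows, 756 with a positive difference (7 months minus P10) and 698 with a negative one, and 4477 had an unadjusted p under 0.05. Among the largest positive differences were Serpinb1c (5.18, SE 0.91), Sprr1a (5.09), the collagen Col11a1 (4.17) and the glucagon receptor Gcgr (4.0). Col11a1 had only 3 counts in the 7-month controls, so the size of its difference is uncertain. Without 7-month mutant 1 Col11a1 came to 3.56 and Gcgr to 3.32, and Sprr1a to 5.94 without P10 mutant 3. Among the largest negative differences outside divided rows were the retinoic acid hydroxylase Cyp26b1 (-2.91, SE 0.60, adjusted p = 0.0163) and Cbs (-2.85). Nppa (3.85, adjusted p = 0.0199), Nppb (1.98, 0.0286) and Myh6 (-1.02, 0.0156) were called, and Myh7 was not (2.89, SE 1.48, 0.235). Without P10 control 1 Nppa came to 3.05 and was not called. Fitted differences of -12.29 for the non-coding row of Sh3kbp1 and -9.79 for the coding row of Ano4 rest on groups with no counts. The Sh3kbp1 row came to -11.55 without 7-month control 3 and -13.08 without 7-month mutant 2, and with rows summed Sh3kbp1 and Ano4 were at -0.46 (adjusted p = 0.135) and -0.74 (0.106).

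The interaction count moved with the tool, the design and most libraries. Voom called 4790, a fit with the replicate number as a block 850 and a fit with the male share, chosen after the data were seen, 913. The count was 162 without P10 control 1, 703 without P10 control 3, 616 without P10 mutant 1, 289 without P10 mutant 2, 643 and 588 without 7-month control 2 or 3, and 748 and 456 without 7-month mutant 1 or 3. It was 2543 without 7-month control 1 and 2463 without 7-month mutant 2, and within 1.5 times without P10 control 2 or P10 mutant 3. Serpinb1c, Sprr1a, Col11a1 and the Sh3kbp1 row each lost their call without P10 control 1 (adjusted p up to 0.0632), Myh6 without P10 mutant 2 (0.0523), and Cyp26b1 without P10 control 1, P10 control 3 or P10 mutant 2 (up to 0.0725). Cbs lost it without those 3 libraries, P10 mutant 1 or 7-month control 3 (up to 0.0945). Nppa lost it without P10 control 1, P10 mutant 1 or 2, 7-month control 2 or 3, or 7-month mutant 3 (up to 0.0638), and Nppb without any of these 6, P10 control 3 or 7-month mutant 1 (up to 0.104). Gcgr and Ano4 kept the call in all 12 fits.

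Calls at P10 and 7 months overlapped in 2 genes, both higher at both stages, against 0.787 for independent lists in that direction. Across the 15478 rows, which are not independent replicates, the log2 fold changes of the 2 stages had a Pearson correlation of 0.014 and a Spearman correlation of -0.14. Over the 9698 rows above 5 CPM these were -0.15 and -0.19.

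With age, 50.2% of the rows changed in control hearts. From P10 to 7 months most listed proliferation, matrix and fetal genes fell, and most of those of fat and ketone use rose. None of these list results held with an estimated correlation. Troponin Tnni1, the slow skeletal isoform of the young heart, fell from 384 ± 215 to 0.260 ± 0.0689 CPM (log2 fold change -10.58, SE 0.53, adjusted p = 3.03e-07, and -9.93 without P10 control 3), and elastin, Eln, from 788 ± 69.7 to 21.8 ± 3.59 CPM (-5.18, SE 0.51). Bdh1 rose from 0.293 ± 0.263 to 108 ± 13.8 CPM (7.95, SE 0.24, adjusted p = 2.1e-10), and Jarid2 fell by 1.00 (adjusted p = 1.02e-05). Of 15478 rows, 3890 rose and 3880 fell.

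Further falls with age were Sox11 (-6.39, and -5.79 or -7.67 without 7-month control 1 or 3), Cpa1 (-5.77), Cthrc1 (-5.68), Col9a2 (-5.33) and Col26a1 (-5.03). Col11a1 had 3 counts at 7 months and was 136 times higher at P10 (95% counting interval 46.3 to 665), Ly6h, with 1 count, 52.0 times (8.88 to 2101), and Nipal4, with 3 counts, 33.2 times (11 to 164). Without 7-month control 1 Ly6h had no count at 7 months and was at least 11.2-fold higher at P10, and Nipal4 was 64.0 times higher (11.2 to 2558). Rises included the methyltransferase Inmt (8.06). Genes with no count in P10 controls were Sco2, at least 77.2-fold higher at 7 months, Pck1, at least 33.1-fold, Cd209b, at least 31.4-fold, the coding row of Ano4, at least 135-fold, and the non-coding row of Sh3kbp1, at least 76.1-fold. Without P10 control 1 or 3 each of these 5 bounds came to 0.521 or 0.482 of the value given. Without 7-month control 3 the bound was 11.3 for Pck1, which held 2.59 CPM in that library and 0.515 and 0.194 in the others, and 46.1 for the Sh3kbp1 row. The mean log2 CPM of the adipocyte markers was 3.10 in 7-month control 3 and 1.66 and 0.530 in 7-month controls 1 and 2. With 1 count at P10, Cfd was 334 times higher (59.5 to 13216) and Acsm5 271 times (48.4 to 10757). Cfd was at least 58.0-fold higher without P10 control 1, and 161 times (28.7 to 6369) and 116 times (20.2 to 4615) without P10 control 3 or 7-month control 3. Acsm5 was 142 times higher (25.2 to 5608) without P10 control 1 and at least 43.6-fold without P10 control 3. With rows summed, Ano4 rose by 1.1 (adjusted p = 0.000851), Cd209b by 6.22 and Sh3kbp1 stood at -0.04 (0.816). The adipocyte gene Cfd lost its call without any P10 control, 7-month control 1 or 7-month control 3 (adjusted p up to 0.189) and held 0.415 to 8.65 CPM in the 3 controls of 7 months.

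Camera called 22 of 45 lists with age, and only dilated cardiomyopathy disease genes held with an estimated correlation (19 of 24 rose, also adjusted over the list alone, median 0.71, adjusted p = 0.0232 with an estimated correlation). All 31 cell cycle genes fell, also adjusted over the list alone (median -2.72, Aurkb -3.63, Ccnb1 -3.59, adjusted p = 0.224 with an estimated correlation). Extracellular matrix genes fell in 21 of 32, with 23 adjusted over the list alone (median -1.88, Eln -5.18, Mfap4 -4.47, adjusted p = 0.394 with an estimated correlation). Fetal growth and imprinted genes fell in 14 of 17, also adjusted over the list alone (median -2.28, Dlk1 -5.97, or -5.08 without P10 control 3, Mest -4.86, adjusted p = 0.144 with an estimated correlation). Fetal and skeletal sarcomere isoforms rose in 1 and fell in 9 of 12, also adjusted over the list alone (median -1.53, Tnni1 -10.58, or -9.93 without P10 control 3, Myl7 -4.70, adjusted p = 0.482 with an estimated correlation). The Myl7 call was lost without P10 control 1 or any 7-month control (adjusted p up to 0.0729). Myl7 and Myl4 are atrial markers too, a list in which 1 rose and 5 fell of 8, with 1 and 6 adjusted over the list alone (median -1.34, not called, adjusted p = 0.56, and 0.755 with an estimated correlation). Its mean log2 CPM was 4.47 and 4.24 in P10 controls 1 and 3 and 2.05, 2.67 and 2.89 in 7-month controls, and how much atrial tissue each library held is not known. Ketone and branched-chain amino acid genes rose in 13 and fell in 1 of 14, also adjusted over the list alone (median 1.78, Bdh1 7.95, Ppm1k 2.63, adjusted p = 0.224 with an estimated correlation). Fatty acid oxidation genes rose in 22 of 25, also adjusted over the list alone (median 0.99, Lpl 2.35, Ech1 1.68, adjusted p = 0.394 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 28 of 35, with 32 adjusted over the list alone (median 0.59, Cox7a1 1.54, Ndufs1 1.32, adjusted p = 0.47 with an estimated correlation). Adult sarcomere genes rose in 16 of 20, also adjusted over the list alone (median 0.59, Tcap 2.18, Lmod2 1.70, adjusted p = 0.144 with an estimated correlation). All 15 interferon response genes rose, also adjusted over the list alone (median 1.51, Ifit1 3.09, Ifit3 2.61, adjusted p = 0.42 with an estimated correlation). Macrophage markers rose in 14 and fell in 1 of 15, also adjusted over the list alone (median 1.41, Ccr2 3.06, Cd163 2.33, adjusted p = 0.349 with an estimated correlation).

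The sex of the animals is not given in the labels, and X- and Y-linked transcripts differed between libraries. All 6 libraries of 7 months held Y-linked transcripts (67.1 to 87.8 CPM summed over Ddx3y, Eif2s3y, Kdm5d and Uty) and under 1 CPM of Xist, the transcript of the inactive X chromosome. So did P10 control 1 and P10 mutant 2. P10 mutant 1 held 376 CPM of Xist and 0.0753 CPM of Y-linked transcripts. P10 control 3, P10 mutant 3 and the shallow P10 control 2 held both, with 236, 291 and 117 CPM of Xist and 33.8, 34.4 and 26.6 CPM of Y-linked transcripts, in control 2 from 35 and 8 counts. Stage and sex therefore overlap in the age comparison. The male share of each library was added to the fit, a choice made after the data were seen. This left 2 calls at P10, 2398 at 7 months, 913 for the interaction and 6768 with age. For this fit the share was the sum of these Y-linked genes over its 7-month mean, at most 1. At 7 months, where all libraries looked male, it was 0.973, 1 and 1 in controls and 0.914, 0.942 and 0.892 in mutants. There the covariate followed genotype, so the counts at 7 months and for the interaction do not show an effect of sex.

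**Figure D3:**
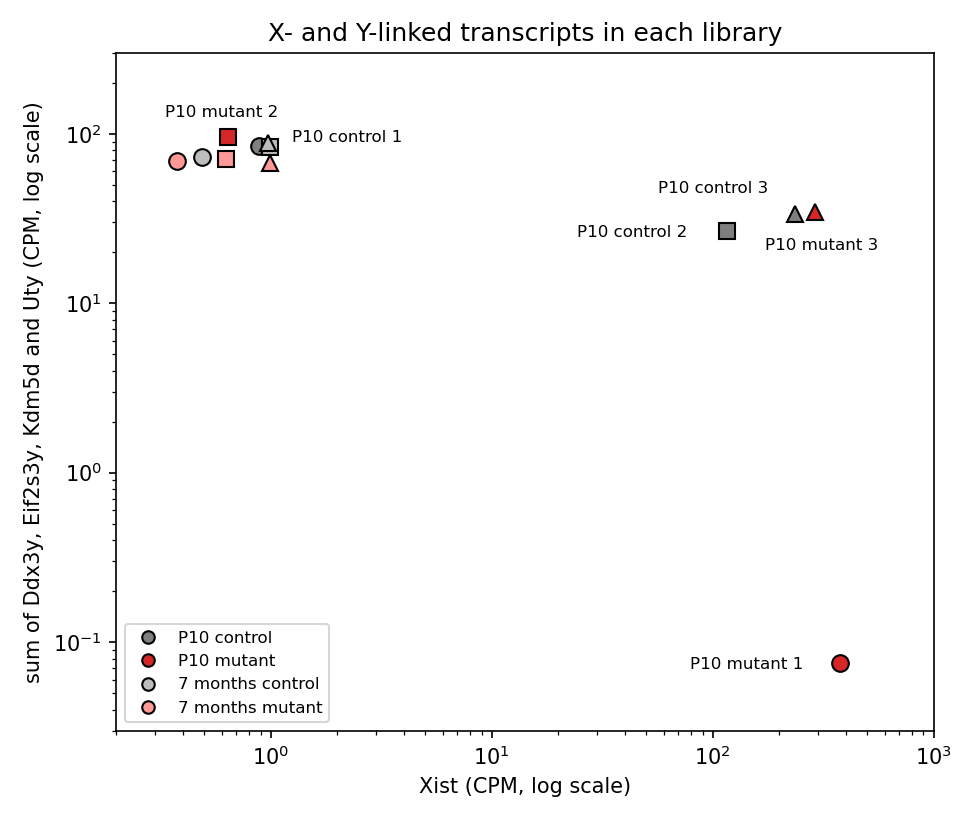
Xist (x axis) against the sum of 4 Y-linked genes (y axis), both in CPM on log scales, with a point per library, colour for the group and marker shape for the replicate number. The 6 libraries of 7 months, P10 control 1 and P10 mutant 2 lie at upper left, P10 mutant 1 at lower right (376 CPM of Xist), and P10 controls 2 and 3 and P10 mutant 3 hold both kinds of transcript.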

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

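The tests of cell share, atrial tissue, summed rows, lanes, leakage and pooled sexes were chosen only after the result was seen, unlike those of Cre, of 7-month reads in the shallow library and of other splits of the samples. The genes and lists below drew attention because the genotype effect differed between 7 months and P10 by the interaction test of edgeR (genes) or camera (lists). That test called 1454 rows. Of 60 splits drawn 1 gave as many, the real split, and the highest other gave 602. A split that mixes 7-month mutants with 7-month controls removes the 7-month difference, and such splits gave at most 24, so they do not test the interaction alone. Only 4 of the 60, with 1454, 602, 313 and 203 calls, kept these groups apart, too few for a share under 0.05. In the split with 602 the 3 P10 libraries that hold both Xist and Y-linked transcripts also stood together, and what that adds was not separated. With the male share as a covariate, which also followed genotype at 7 months, the real split gave 913. For the other comparisons 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many calls: 9 at P10 with 1 as the highest other, 2949 at 7 months with 3, and 7770 with age with 0.

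Of the genes named for the genotype comparisons, 61 had such a difference, 26 positive and 35 negative (log2 scale, 7 months minus P10). Among matrix and fibroblast genes it was 3.35 for Cilp, 3.73 for Ltbp2, 1.63 for Col1a1, 1.52 for Col3a1 and 4.17 for Col11a1 (3 counts in 7-month controls). Among stress, growth and hormone genes it was 3.85 for Nppa, 1.98 for Nppb, 3.35 for Gdf15, 3.89 for Nrg1, 5.09 for Sprr1a, 1.52 for Cdkn1a, 1.32 for Phlda3, 1.52 for Sdf2l1, 1.03 for Creld2, 1.63 for Aurkb, 1.39 for Birc5 and 4.0 for Gcgr. It was 5.18 for Serpinb1c, 2.77 for Lrp8, 2.88 for Mgam, 2.99 for Prrx2, 1.24 for C1qb, 0.99 for Lyz2 and 0.80 for Vwf. Among metabolic genes it was -2.34 for Pfkfb1, -1.26 for Etfdh, -0.88 for Ech1, -1.66 for Bdh1, -1.59 for Ppm1k, -1.08 for Sucla2, -0.86 for Suclg2, -0.65 for Idh2, -0.90 for Mdh1, -1.14 for Ndufs1, -0.88 for Uqcrc2, -1.07 for mt-Atp6, -0.82 for mt-Nd4, -1.12 for mt-Nd6 and -2.85 for Cbs. Among genes of contraction and excitation it was -1.02 for Myh6, -0.97 for Ryr2, -1.03 for Slc8a1 and 2.70 for Kcne1. Among regulators it was -0.65 for Jarid2, -1.36 for Irx2, -1.92 for Irx1, -1.45 for Esrrg, -0.78 for Esrrb, -0.75 for Mef2a, -1.81 for Epop and -2.91 for Cyp26b1. The rest were Lrig1 at -0.93, Dapk1 at 0.69, Flt1 at -0.66, Tmem150c at -2.54, Uckl1os at -2.73, Cngb3 at -2.46, Amph at -1.97, and the divided rows of Fam120b at -1.82, Ano4 at -9.79 and Sh3kbp1 at -12.29. Of these 61 calls, 51 ended without P10 control 1, 5 without P10 control 2, 21 without P10 control 3, and 24, 33 and 13 without P10 mutants 1, 2 and 3. At 7 months 2, 18 and 21 ended without controls 1, 2 and 3, and 16, 1 and 26 without mutants 1, 2 and 3. Ano4, Fam120b, Mgam, Tmem150c, Sdf2l1, Cdkn1a, Phlda3, Kcne1 and Gcgr kept the call in all 12 fits. Without 7-month mutant 1 the difference was 2.98 for Ltbp2, 2.44 for Gdf15, 3.56 for Col11a1, 3.32 for Gcgr and 2.22 for Prrx2. Prrx2 stood at 3.69 without 7-month control 2, Sprr1a at 5.94 without P10 mutant 3, Nrg1 at 4.81 without P10 mutant 2, Nppa at 3.05 without P10 control 1, Uckl1os at -2.06 without P10 mutant 1, and the Sh3kbp1 row at -11.55 without 7-month control 3 and -13.08 without 7-month mutant 2.

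Of 45 lists, 20 had such a difference by camera, given here as the median over members. It was positive for extracellular matrix (1.70), genes tied to Jarid2 in earlier heart work (2.11), fetal and skeletal sarcomere isoforms (2.09, beside 2.03 for atrial markers, which share Myl7 and Myl4 with them and were not called), heat shock proteins (1.20), cardiac stress genes (1.19), cell cycle (0.84), inflammation and acute phase (0.73), macrophage markers (0.73), fibroblast markers (0.70), the integrated stress response (0.49) and the unfolded protein response (0.38). It was negative for ketone and branched-chain amino acid breakdown (-0.94), mitochondrially encoded proteins (-0.84), the tricarboxylic acid cycle (-0.76), fatty acid oxidation (-0.75), calcium handling (-0.47), nuclear oxidative phosphorylation (-0.42), dilated cardiomyopathy disease genes (-0.36), adult sarcomere (-0.31) and cardiac transcription factors (-0.26). Camera with an estimated correlation called 0 lists for this difference, with 7 at an unadjusted p under 0.05 and adjusted p from 0.254 to 0.474 with an estimated correlation for these 20, while fry called 15.

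Most listed genes of fatty acid oxidation, ketone use and the tricarboxylic acid cycle fell in 7-month mutants, though their list calls did not hold with an estimated correlation. A smaller share of heart muscle cells, with the other cell types in unchanged proportion, would raise all their markers alike. Yet the fibroblast list lay above the endothelial list by 0.87 ± 0.063 (mean log2, SD over 3 mutant libraries). This argues against that case alone. A smaller share in which fibroblasts gain over endothelial cells would give such a gap, so a smaller muscle share stays open. Atrial tissue in mutant 1 alone, where the atrial genes were high, would leave no fall in the others. Yet the median change of the fatty acid oxidation list was -0.50 ± 0.17 in mutants 2 and 3 (SD over these 2 libraries). Its mean log2 CPM was 8.55 and 8.33 there and 8.73, 9.10 and 8.91 in controls. The atrial list also lay above the control mean in mutants 2 and 3, by 0.45 and 0.73. The fall was thus not confined to mutant 1, while atrial tissue across the mutants stays open. Presence of Cre and loss of Jarid2 cannot be told apart, since 0 of 6 control hearts carry Cre and all mutants do. Loss of Jarid2 may account for the fall, as a hypothesis beside Cre, a smaller muscle share, atrial tissue and the state of a failing heart. No library separates these.

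The coding rows of Ano4 and Fam120b were called at P10, and with coding and non-coding rows summed Ano4 came to 0.34 and Fam120b to -0.10, neither called. Division of the reads of a gene between its rows may therefore account for both calls. Division at random from run to run is in line with Ano4, whose coding share differed by over 20 percentage points between lanes in 7 of 11 libraries, although it was 0% in both lanes of the deep P10 controls. For Fam120b 0 of 12 libraries differed by that much (largest difference 18.2 points). Its coding share was 7.20%, 8.86% and 4.39% in P10 controls and 19.1%, 22.9% and 18.2% in P10 mutants, the values behind the call itself. The limit of 20 points exceeds this gap between the groups, and the lanes of P10 mutant 2 differed by 11.9 points. The lanes therefore cannot decide on random division of Fam120b. Random division stays open for Fam120b, as does a true difference in transcript use or a strain variant, neither of which was tested.

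Xist and Y-linked transcripts stood together in P10 control 3, P10 mutant 3 and P10 control 2. Reads leaking into all libraries alike would bring Y-linked transcripts to P10 mutant 1 too. Its male share, here relative to the mean of P10 control 1 and P10 mutant 2, was 0.0836%. In P10 control 3 and mutant 3 that share was 37.5% and 38.2%. A mixing of RNA or reads between particular libraries could spare P10 mutant 1 and was not tested. Reads of 7-month libraries in P10 control 2 were looked for with 5 genes (Bdh1, Cxcl14, Hsd11b1, Ifi205 and Inmt). These were picked from the same data, under 0.5 CPM in the other P10 controls and at 20 CPM or more in 7-month controls. In P10 control 2 they stood at 0.870% of their 7-month level (1 count, upper 95% bound 7.95%). This argues against a share above that bound, and not against a smaller one. Hearts of both sexes pooled in a library may account for control 3 and mutant 3, whose male and female shares added up to 1.00 and 1.16, while control 2 (0.605, from 35 Xist and 8 Y-linked counts) is too shallow to decide. Any mixture of male and female RNA would give such sums, so they do not tell pooled hearts from mixing between particular libraries. The labels mention no pooling, and no biological explanation was tested.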

How the results depend on the processing

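Fits with summed rows and with the male share were chosen after the data were seen, the other alternatives before. Of 3028 single gene and list results under the alternatives, 2755 kept direction and side of the threshold, 245 lost the call, 26 gained one and 2 reversed. These totals pool settings that changed little, such as effective lengths (136 of 136 the same), with stricter ones. With an estimated correlation 37 of 42 list results lost the call. Of the named genes called, 7 of 8 at P10 lost the call in at least 1 fit with a library left out. The same held for 13 of 61 at 7 months, 10 of 12 for the interaction and 2 of 37 with age. The reversals came from summing rows: Fam120b at P10 became -0.10 and Sh3kbp1 with age -0.0446, because the divided reads were joined. Counts at P10 were 33 with DESeq2, 38 with voom, 51 with only the libraries compared, 1 and 3 with lane 3 or 4 alone, 2 with the male share and 1 to 3 with a library left out. At 7 months they were 1891 with DESeq2, 6194 with voom, 1826 with only the libraries compared and 1638 to 3330 with a library left out. For the interaction they were 4790 with voom, 850 with the replicate number as a block, 913 with the male share and 162 to 2543 with a library left out. The overlap of P10 and 7-month calls was 8 with DESeq2, 12 with voom, 11 with only the libraries compared, 4 with the block, 0 and 1 with lane 3 or 4, 1 with the male share and 0 to 3 with a library left out. The Jarid2 interaction was -0.59 with the block (not called, adjusted p = 0.063) and -0.74 to -0.56 with a library left out. Single lanes and left-out libraries hold fewer reads or samples; for the rest the cause was not tested. With an estimated correlation, 0 lists were called at P10, 0 at 7 months and 1 with age, and fry, which asks another question, called 1 at P10 and 34 with age. Replicate numbers were not taken to pair the samples. Same-number correlations of control and mutant were -0.0143 to 0.0569 at P10 and -0.0134 to 0.109 at 7 months, and with 3 libraries per group they cannot exclude a shared litter or batch. Scaling by DESeq2's size factors kept all 178 results compared. P10 control 2, at 3.33 CPM per read after TMM scaling, cannot show genes of a few CPM, which limits P10 comparisons of low genes to 2 deep controls.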

Other observations

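The test of age against genotype was written before its result was seen, while the lists and members described here, and the chromosome of the P10 genes, were chosen after. At 7 months several groups held genes called in both directions, and none of the lists in this paragraph was called. Among dilated cardiomyopathy disease genes 4 rose and 5 fell of 24, with 6 and 7 adjusted over the list alone (median -0.05, camera adjusted p = 0.733). Ankrd1, a stress-responsive protein of the sarcomere, stood at 2.15, dystrophin Dmd at -1.21, and the desmosome genes Dsc2 and Dsg2 at -1.02 and -0.80. Glycolysis genes rose in 3 and fell in 6 of 23, with 4 and 7 adjusted over the list alone (median -0.02, adjusted p = 0.546). The muscle glucose transporter Slc2a4 stood at -0.67 and the platelet form of phosphofructokinase, Pfkp, at 1.08, and its muscle form Pfkm at -0.46. Adrenergic signalling genes rose in 2 and fell in 3 of 15, with 5 and 6 adjusted over the list alone (median -0.17, adjusted p = 0.557). The receptor Adra1a stood at -1.64 and the receptor kinase Grk5 at 1.1. Kcnj2, Kcnj3 and Kcnj11, 3 of the 7 genes that fell in the ion channel list, in which 4 rose, stood at -1.44, -1.17 and -1.29. Of 15 circadian clock genes 2 fell, Nr1d1 at -0.40 and Nr1d2 at -0.57 (median -0.47, adjusted p = 0.316). Calls of the genes in this paragraph were not followed with single libraries left out.

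Of the 8 called genes named at P10, Irx1, Irx2 and Dapk1 lie on chromosome 13, as Jarid2 does, at 71958232, 72624430 and 60601723 against 44730774 for Jarid2. No test of this was made.

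A hypothesis is that 7-month mutants return in part toward the P10 pattern of expression. Over 15478 rows, which are not independent replicates, the covariance of the log2 fold changes with genotype at 7 months and with age in controls was -0.32. Both changes share the 7-month controls, which alone gives a negative value. In 20 simulations with no effect of age or genotype it was -0.083 on average and -0.0991 at the lowest. The simulations drew rows independently and gave all groups the same dispersion. Yet the chi-square per degree of freedom between replicates was 36.7 to 134 in 7-month controls and 34.9 to 103 in 7-month mutants. It was 16.4 to 57.3 between deep P10 replicates. How much of the observed covariance comes from the sharing is therefore not settled. The Pearson correlation was -0.40 against -0.46 in those simulations, and the Spearman correlation was -0.35 against -0.44 to -0.41. True changes with age or genotype add variance that the simulations lack, so these correlations cannot speak for or against the hypothesis. Over the 10660 rows at 5 CPM or more in either control group, the covariance was -0.18 against -0.027 and the correlation -0.43 against -0.46. Of the 1427 genes lower in mutants 806 had risen with age (359 for independent lists), and of the 1522 higher 712 had fallen (382), counts that share those controls too. The covariance has the sign that the hypothesis predicts, which the shared controls give as well, and the correlations do not decide. Sex also differs with age in these libraries, so the hypothesis stays open.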
